A study of Mus musculus with 2 samples.

How the data were processed

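Single-cell suspensions of kidney cortex from 12-week-old mice were measured with a 3' droplet kit (version 3.1, per the labels), with 1 library from mice expressing I-PpoI in podocytes and 1 from wild-type mice. The deposited values are whole-number counts of UMIs per gene and barcode, which the authors made with Cell Ranger against an mm10 reference package, per the labels. The labels name Cell Ranger version 3.1 and the file headers version 6.0.2, and which of them produced the counts is not settled here. The labels also name Seurat version 3 for later steps, but the deposited values are not normalized, since all are whole numbers from 1 upward. The barcodes in the files each held at least 500 UMIs. Gene symbols came from the files, and 30934 of the 31053 gene identifiers (99.6%) matched GENCODE release 21 of the mouse, on the same build, which gave the coordinates.

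Cells were kept with at least 200 detected genes and at most 50% of UMIs from mitochondrially encoded genes. In the I-PpoI library 1144 barcodes (21.7%) lay under the gene limit and 1058 (20.1%) over the mitochondrial limit, and in the wild-type library 1732 (31.3%) and 2054 (37.1%), which left 4091 and 3217. Doublets were scored per library with Scrublet in scanpy. Its automatic threshold marked 5 (0.122%) and 3 (0.0933%) barcodes, under the floor of 0.5%, so the top 4% of scores was left out as planned for that case: 145 barcodes (3.54%) and 118 (3.67%) after ties. The remaining 3946 and 3099 cells held 34998226 and 19590970 UMIs. RNA from other cells in the droplets was not removed.

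Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and logged, and 2000 variable genes gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1. The 30 clusters were named from markers of 21 cell types fixed before the data were examined, so cell classes are rebuilt and can differ from those of the study. A marker counted where it reached 25 CPM and 4-fold over the median cluster, with 10 CPM added to each, and a name needed 3 such markers. A cluster also stayed unnamed where its 10 leading genes held more markers of another class than of its best match. These thresholds, and 2 rules that left clusters unnamed (haemoglobin genes with 8 or more markers of another class, and 3 or more cell cycle genes among the 10 leading genes), were set after the data were seen. In all, 5 clusters stayed unnamed and 13 classes were compared.

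UMIs were summed per library and class and expressed as CPM of the class total. Sums have exact Poisson intervals, ratios exact conditional binomial ones, and shares of cells exact Clopper-Pearson ones, all of 95%. A gene absent from 1 library is given as a bound against 3 UMIs in that library's class, written as at least or at most. This bound is a floor value and not a 95% limit, and the exact interval is wider. For 37 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 10 UMIs in the class and 0.5 counts added to each sum, with 3 members needed. The interval over members is a binomial (order statistic) interval of 95% for this median. It treats the members as independent and covers neither counting error nor variation between libraries. The percentile of the median among 10000 random lists of the same size, matched on expression in 20 bins, describes these libraries and is no test. No p-values were computed, since cells are not replicates.

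Genes were named by a rule fixed before the data were examined. Genes of a class with at least 50 UMIs (20 where a library had under 100 cells of it) were ranked by the interval bound of their ratio nearest to 1. The first 12 each way were named in proximal tubule-like cells and the first 5 each way elsewhere. Mitochondrially encoded, ribosomal protein, haemoglobin and model genes were left out and, outside the tubule, so were genes with more CPM in proximal tubule-like cells. Members of the gene lists were added as examples, and some genes are not reported here.

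The steps were tested on simulated counts for each main class, with 200 genes changed by known folds. Counts were drawn with Poisson error alone from the pooled profile of the class. The check therefore covers counting error and not variation between cells, clusters or libraries. In proximal tubule-like cells (12376 genes) intervals of unchanged genes held the true ratio in 95.9%, and all genes with 50 UMIs or more changed 2-fold or 4-fold had intervals above 1. In endothelial-like cells (11402 genes) these shares were 95.8%, 97.5% at 2-fold and 100% at 4-fold, in macrophage-like cells (11248 genes) 96.9%, 78.3% and 98.8%, and in T cell-like cells (7455 genes) 97.1%, 82.1% and 100%. A list of changed genes came out at percentile 100 in each. Lists of unchanged genes spread between percentiles 0.77 and 95.0 in the first class, 0.77 and 91.0 in endothelial-like, 0.04 and 99.5 in macrophage-like and 0.92 and 89.5 in T cell-like cells, so a single extreme percentile can arise without change.

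CD8 and Klrk1 cells were counted by a UMI, at full depth and with each cell thinned to 1000 UMIs. Alternatives covered the cell filters, doublets, resolution, class assignment, denominator, scaling, the minimum for list members, the pseudocount and equal weight per cell. The tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9, with seed 1. Integration of the libraries, trajectories and receptor sequences were left out.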

Results

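The series profiled dissociated kidney cortex of 12-week-old mice by droplet single-cell RNA sequencing, in which each transcript is counted by a unique molecular identifier (UMI). There was 1 library from mice expressing I-PpoI in podocytes and 1 from wild-type mice. I-PpoI is a homing endonuclease that makes DNA double-strand breaks, and podocytes are the epithelial cells of the glomerular filter. The labels do not say how many mice each library holds. The I-PpoI library held 5268 barcodes with 37811289 UMIs, and the wild-type library held 5536 barcodes with 27793633 UMIs. Of these, 3946 I-PpoI cells (median 6627.5 UMIs and 1955 genes) and 3099 wild-type cells (median 3483 UMIs and 1348 genes) were compared. Their median share of UMIs from mitochondrially encoded genes was 3.32% and 14.3%. With 1 library per group there is no replicate check on any difference. Values of both libraries are given with intervals of 95% that cover counting error only. Intervals over members of a gene list instead cover the spread of its genes, taken as independent. Folds compare CPM, the UMIs of a gene scaled to the total of the summed cells of a class, I-PpoI over wild-type.

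The first comparison asked which cells the cortex of each library held, in classes rebuilt from clusters and markers. Macrophage-like cells, the resident and recruited phagocytes, made up 34.2% of I-PpoI cells (1351 cells, interval 32.8 to 35.7%) and 5.45% of wild-type cells (169 cells, 4.68 to 6.31%), a ratio of 6.28 (5.35 to 7.41). Fibroblast-like cells, which make collagen, were at 5.85% against 0.581%, a ratio of 10.1 (6.24 to 17.3). With at least 500 genes per cell these ratios were 32.4 for macrophage-like and 24.8 for fibroblast-like cells, and 143 of 164 wild-type macrophage-like cells that passed fell into unnamed clusters. Neutrophil-like cells were at 4.61% against 0.387%, a ratio of 11.9 (6.65 to 23.5), and T cell-like cells at 6.56% against 1.94%, a ratio of 3.39 (2.55 to 4.57). Proximal tubule-like cells, the epithelium that takes up most of the filtered solutes, made up 11.0% (436 cells, 10.1 to 12.1%) against 43.5% (1347 cells, 41.7 to 45.2%). Their ratio was 0.254 (0.228 to 0.283), which includes a cluster of uncertain name (cluster 4, described below), and 0.0373 without that cluster. It was 0.0280 at a resolution of 0.5, 0.0193 with a mitochondrial limit of 25 percent and 0.0879 by each cell's marker score.

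The other epithelial classes of the nephron were mostly lower as well. Thick ascending limb-like cells, marked by the uromodulin gene Umod, held 0.634% of I-PpoI cells and 7.84% of wild-type cells, a ratio of 0.0808 (0.0513 to 0.122). This count leaves out the unnamed cluster 0 (243 I-PpoI and 49 wild-type cells). The best match of that cluster was this segment, with 7 of 8 markers detected. Cells like distal convoluted tubule, connecting tubule and principal cells stood at 0.887% against 5.45%, a ratio of 0.163 (0.110 to 0.235), and intercalated-like cells, which handle acid and base, at 1.17% against 1.81%, a ratio of 0.645 (0.427 to 0.970). Parietal epithelial-like cells, which line the glomerular capsule, were higher at 2.08% against 0.774%, a ratio of 2.68 (1.69 to 4.42). Endothelial-like cells made up 8.21% against 21.6%, a ratio of 0.381 (0.333 to 0.436). The ratio was 1.88 (1.14 to 3.20) for dendritic-like cells, 0.785 (0.457 to 1.35) for B and plasma-like cells and 0.925 (0.669 to 1.28) for mesangial, mural and renin-like cells, the last 2 with intervals that include 1. Outside the proximal tubule-like class the ratio was 1.19 (0.721 to 2.04) for dendritic-like, 0.499 (0.291 to 0.857) for B and plasma-like and 0.588 (0.425 to 0.815) for mesangial, mural and renin-like cells. The directions stayed the same, but whether each interval includes 1 depends on the denominator.

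**Figure D1:**
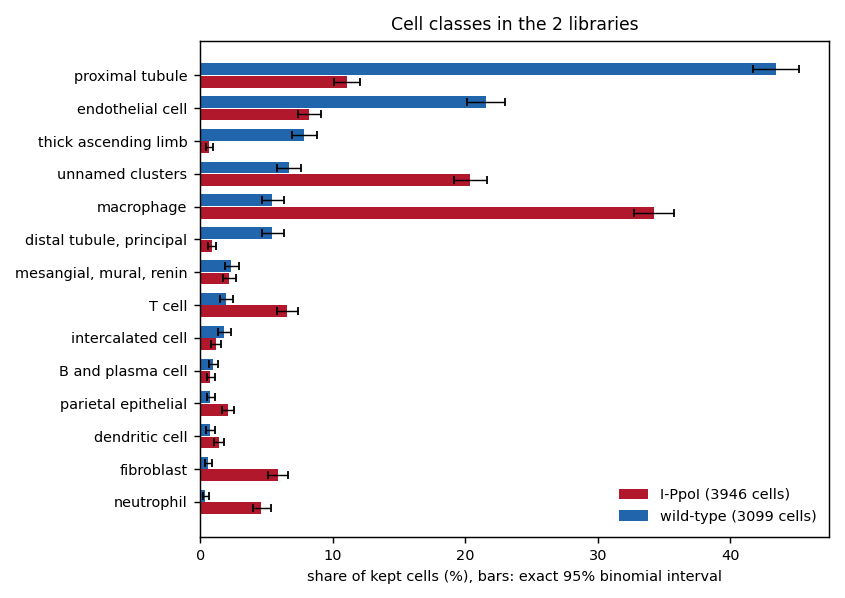
Share of kept cells (%, horizontal axis) in each rebuilt cell class of the I-PpoI library (red, 3946 cells) and the wild-type library (blue, 3099 cells), 1 library per group; whiskers are exact binomial intervals of 95%. Macrophage-like cells stand at 34.2% against 5.45% and proximal tubule-like cells at 11.0% against 43.5%; 372 of the 436 I-PpoI proximal tubule-like cells belong to cluster 4, whose name depends on the settings.

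Shares of a whole move together, so a lower tubular share raises every other one. Counted only among cells outside the proximal tubule-like class, the ratio was 3.99 for macrophage-like, 2.15 for T cell-like and 0.242 for endothelial-like cells. Cells of the named immune classes, with an unnamed cluster led by Arg1 and Chil3 included, made up 53.3% (51.7 to 54.8%) against 9.78% (8.75 to 10.9%), a ratio of 5.45 (4.83 to 6.17). Not counted were the unnamed clusters 5 (215 I-PpoI and 66 wild-type cells) and 21 (54 and 9), which also carried macrophage markers. Among the immune cells counted, the T cell-like share was lower in the I-PpoI library, with 12.3% against 19.8% and a ratio of 0.622 (0.468 to 0.838). On that denominator the ratio was 0.345 for dendritic-like cells (0.208 to 0.588) and 1.15 for macrophage-like cells (0.981 to 1.36), an interval that includes 1. It was 0.144 for B and plasma-like cells (0.0840 to 0.247) and 2.19 for neutrophil-like cells (1.22 to 4.31). Clusters left unnamed held 20.4% of I-PpoI and 6.68% of wild-type cells. The largest of them, cluster 0, with 243 I-PpoI and 49 wild-type cells, was led by Lcn2, Krt19, Clu, Krt18, Wfdc2, Sprr2f, Sprr1a, Krt15, Spink12 and Sfn, and stayed unnamed because its leading genes included more markers of urothelium than of its best match, the thick ascending limb. Limits on cell quality bear on these shares: 1058 I-PpoI barcodes (20.1%) and 2054 wild-type barcodes (37.1%) exceeded the mitochondrial limit. With a limit of 25 percent the thick ascending limb ratio turned to 1.32, because that name then went largely to cells of the unnamed cluster 0: 132 of 135 in the I-PpoI library and 38 of 60 in the wild-type library. The ratio for this segment therefore depends on how cluster 0 is named.

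**Figure D2:**
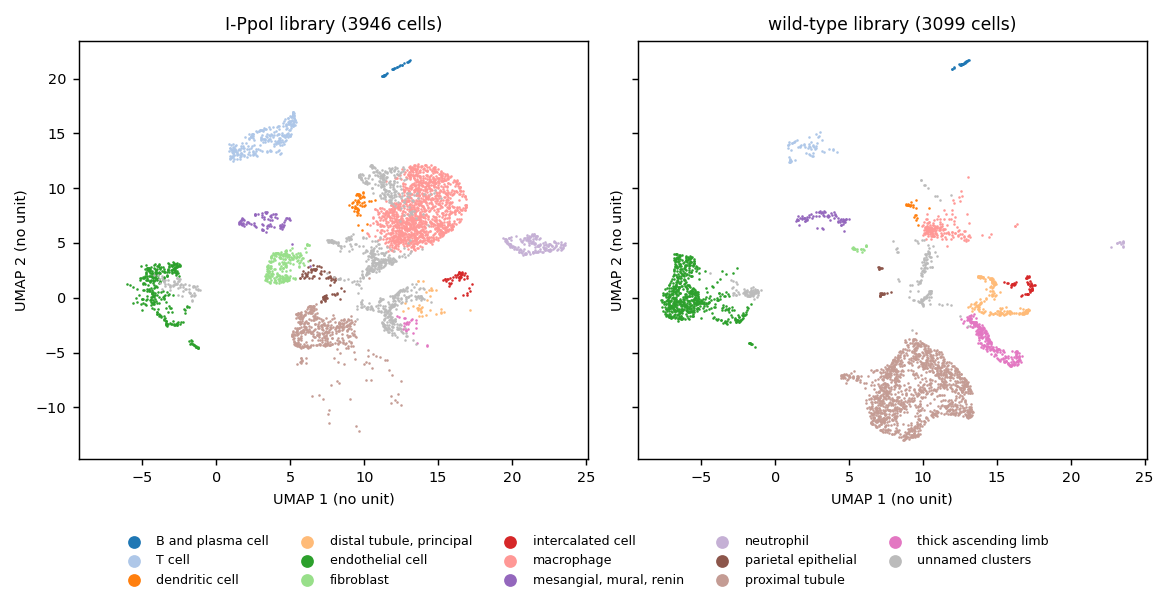
Map of kept cells by gene expression (UMAP, axes without unit), with the I-PpoI library (3946 cells) on the left and the wild-type library (3099 cells) on the right; each point is 1 cell, coloured by its rebuilt class, and grey points are unnamed clusters. Both libraries were embedded together, and the proximal tubule-like points of the libraries lie mostly in different areas.

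Within proximal tubule-like cells, genes of tubular injury were higher in the I-PpoI library and genes of solute transport lower. All 18 measured members of the injury list were higher, with a median log2 ratio of 7.01 (6.78 with genes absent from 1 library at their bound). Spp1, which encodes osteopontin, stood at 251639 against 3057 UMIs, 143-fold higher (138 to 148), and Havcr1, which encodes kidney injury molecule 1, at 1534 against 0 UMIs, at least 889.6-fold higher against a floor of 3 UMIs in the wild-type class. Of 20 solute transport genes 18 were lower, with a median of -1.18, among them Slc34a1, the main phosphate transporter, with a ratio of 0.225 (0.218 to 0.232). The class was made of different clusters in the libraries. Cluster 4 held 372 of the 436 I-PpoI cells and no wild-type cell, whereas the wild-type cells lay in clusters 14, 22, 26, 27, 28 and 29.

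Cluster 4 was itself led by C3, Fgg, Fga, Havcr1 and Gpc3 with the tubular genes Cyp27b1 and Gc, so those genes describe it and are no separate result. It may stand for that library rather than for a cell type. Its name depended on the settings: at a resolution of 2.0, 229 of its 372 cells stayed proximal tubule-like, at 0.5 none did, and by each cell's own marker score 95 did while 199 were nearest to parietal epithelial cells. With at least 500 genes all 325 of its cells that passed stayed proximal tubule-like. Without it the injury median was 1.29, with an interval over members that includes 0 (-0.46 to 3.32). The shared cluster 14, with 47 I-PpoI and 480 wild-type cells, gives a comparison without the cells of cluster 4. The I-PpoI cells of cluster 14 were shallower (median 1036 against 2033.5 UMIs), and RNA from other cells in the droplets was not removed. There the injury list was higher by a median of 1.33 (interval over members 0.36 to 3.12), with all 7 measured members higher, and the transport list stood at -0.45. In cluster 14 Spp1 was 7.50-fold higher (6.76 to 8.32) and Fgg, a fibrinogen chain, 8.56-fold higher (4.67 to 15.2), while Gatm, the first enzyme of creatine synthesis, had a ratio of 0.514 (0.437 to 0.602). Spp1 was also higher in the unnamed clusters 5 (31.77-fold, 10.74 to 155.2) and 16 (5.511-fold, 2.195 to 17.79), both led by haemoglobin genes. Its higher level in cluster 14 is therefore not shown to come from the cells of that cluster.

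The genes named by rank in the whole class mainly describe cluster 4. Higher were S100a6, a calcium-binding protein gene, at 10123 against 7 UMIs (2516-fold, 1221 to 6259), the complement gene C3 at 8658 against 13 (1159-fold, 677 to 2177), and Akap12 at 1834 against 2 (1595-fold, 441 to 13183). The stress factor gene Atf3 was 1075-fold higher (297 to 8888), the adhesion molecule gene Vcam1 670.4-fold (308 to 1829), Anxa2 534-fold (228 to 1647) and the actin-binding Tmsb10 429-fold (271 to 725). The neutrophil chemoattractant Cxcl1 was 813-fold higher (225 to 6726). Absent from the wild-type class were Sox9, a progenitor and repair factor (at least 518-fold higher), Tubb2b (at least 430.3-fold) and Cxcl2 (at least 306-fold). Without cluster 4 the log2 ratio was 4.95 for S100a6 (2.66 to 6.85), 5.45 for C3 (4.14 to 6.72) and 4.56 for Tmsb10 (3.11 to 5.79), while the intervals for Akap12, Atf3, Vcam1 and Cxcl1 included 0.

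Many of the genes lower by rank lead clusters with few or no I-PpoI cells and so describe these clusters in part: Kap, Slco1a1 and Cyp2a4 cluster 22, Slc7a13, Slc22a30, Ces1f and Acsm3 cluster 28, and Slc22a7 cluster 29. Dnase1, which encodes a secreted nuclease, was 35.7 times lower at 72 against 4472 UMIs, the organic anion transporter gene Slco1a1 36.7 times and Slc22a7, with 1 against 256 UMIs, had a ratio of 0.00680 (0.000171 to 0.0382). The amino acid transporter gene Slc7a13 was 28.0 times lower, Akr1c14 54.2 times, Cyp2a4 28.9 times, Cyp2d9 24.0 times and Acsm3 26.4 times. Lpl was 20.9 times lower, and Ces1f and Slc22a30 were each 18.8 times lower. Kap, the androgen-regulated kidney protein gene and the most abundant of these, stood at 1540.4 against 27501 CPM, 17.9 times lower. With a mitochondrial limit of 25 percent, which left cluster 4 outside the class, Slc7a13 and Slc22a30 turned to log2 ratios of 0.27 and 0.24. Without cluster 4 alone the log2 ratio was -0.90 for Kap, -0.69 for Lpl and -0.43 for Slc7a13, and the intervals for Slc22a7, Slco1a1, Akr1c14, Cyp2d9 and Slc22a30 included 0.

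Metabolic lists had mostly lower medians in the whole class. All 11 genes of gluconeogenesis and amino acid metabolism were lower, with a median of -1.43 and Gatm at a ratio of 0.144, Hpd at 0.111 and Ass1 at 0.272, while Pck1 was at 0.967 (0.930 to 1.00). Of 19 genes of fatty acid oxidation and peroxisomes 12 were lower (median -0.54; Acadm 0.414, Cyp4a10 0.372), and Cyp4a14 was 3.28-fold higher (2.83 to 3.81). Nuclear-encoded oxidative phosphorylation genes were lower in 13 of 18 (median -0.31) and mitochondrially encoded ones in all 13 (median -1.42). The last follows the share of mitochondrial UMIs, a sign of cell quality, which was 9.91% in I-PpoI and 25.1% in wild-type cells of the class, with 10.6% and 43.7% of cells above 25 percent. Among 10000 random lists matched on expression, the transport, gluconeogenesis and mitochondrially encoded medians lay at percentile 0, the fatty acid median at 0.0500 and the oxidative phosphorylation median at 3.67. All 10 genes known to be higher in tubules of male mice were lower (median -3.20, percentile 0), and 5 of 8 genes known to be higher in females were higher (median 2.03, percentile 99.9). Without cluster 4 the medians were -0.14 for gluconeogenesis, -0.22 for fatty acid oxidation, 0.17 for nuclear-encoded oxidative phosphorylation, -0.25 for mitochondrially encoded and -0.46 for male-biased genes, so most of these differences lie with that cluster. In cluster 14 the male-biased median was 0.00, with Kap 4.80 times lower.

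Immune genes were higher in the same class. All 14 genes of MHC class I presentation were higher, with a median of 3.52 and H2-K1 12.9-fold higher (11.8 to 14.2). All 8 of MHC class II were higher, with a median of 4.89 and Cd74, the invariant chain, 60.7-fold higher (50.2 to 74.1). Interferon response genes were higher in 20 of 22 (median 3.61, or 3.27 at the bounds), led by Gbp2 at 63 against 2 UMIs (54.8-fold, 14.6 to 462), with Irf1 26.3-fold higher and Bst2 at 186 against 17 UMIs. All 13 chemokine genes were higher (median 5.14, 4.42 at the bounds), with the monocyte attractant Ccl2 at 609 against 1 UMI (1059-fold, 189 to 41920.0). All 10 complement and acute phase genes were higher (4.65, 4.27 at the bounds), as were 13 of 14 matrix genes (5.33, 5.18 at the bounds). The abundant macrophage transcripts Apoe and Cd74 were also higher here, and RNA from other cells in the droplets was not removed. Without cluster 4 the median was 0.73 for interferon response (5 of 9 higher) and 0.98 for MHC class I (8 of 10 higher), both with intervals over members that include 0 (-0.38 to 2.06 and -0.58 to 1.84). In cluster 14 the median was 1.39 for MHC class I, 2.93 for MHC class II and 2.78 for complement.

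For genes tied to DNA damage, 18 of 22 p53 targets were higher with a median of 1.10 at percentile 99.9. Cdkn1a, the cell cycle inhibitor p21, was 30.0-fold higher (19.3 to 49.0), Btg2 219-fold (125 to 425) and Gdf15 22.7-fold (18.8 to 27.6), whereas the canonical targets Mdm2 and Ccng1 stood at ratios of 1.31 (1.07 to 1.59) and 0.768 (0.667 to 0.882). Without cluster 4 the p53 median was 0.26, with an interval over members that includes 0 (-0.042 to 1.47). The double-strand break repair list had a median of 0.40 at percentile 38.7, close to the median of 0.45 over all 12376 genes measured in the class, with Rad50 2.97-fold higher (2.27 to 3.90) and Nbn at 0.743 (0.517 to 1.05). DNA methylation enzymes had a median of 0.68 at percentile 72.4, with Dnmt1 2.03-fold higher (1.46 to 2.83) and Dnmt3a at 0.858 (0.673 to 1.09). Genes of the senescence list were higher in 9 of 11 (median 1.41, percentile 99.2), with Cdkn2a at 44 against 0 UMIs (at least 25.5-fold) and Cdkn2b at 70 against 1 (122-fold, 21.1 to 4878). The list includes Lmnb1, Hmgb1 and Hmgb2 and sets no direction for its members, so the count is no measure of senescence.

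Lists for stress gave mixed values in this class. Apoptosis genes were higher in 14 of 15 (median 1.33), and all 13 genes of ribosome biogenesis were higher (median 0.72, percentile 89.9). The unfolded protein response list was split 6 to 6 (median -0.03), NRF2 targets stood at 0.16 and genes of megalin endocytosis and lysosome at 0.17, with the megalin gene Lrp2 at a ratio of 0.221 and the protease gene Ctsl 3.44-fold higher. Immediate early and heat shock genes, which tissue dissociation can induce, were higher in 15 of 17 (median 4.80, 4.43 at the bound), with Fos 70.4-fold higher. Totals without mitochondrial genes lowered every log2 ratio of this class by 0.27 and median-of-ratios scaling by 0.39, which turned the medians of the NRF2 and megalin lists below 0, and the second brought Mdm2 and the break repair list to about the wild-type level.

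**Figure D3:**
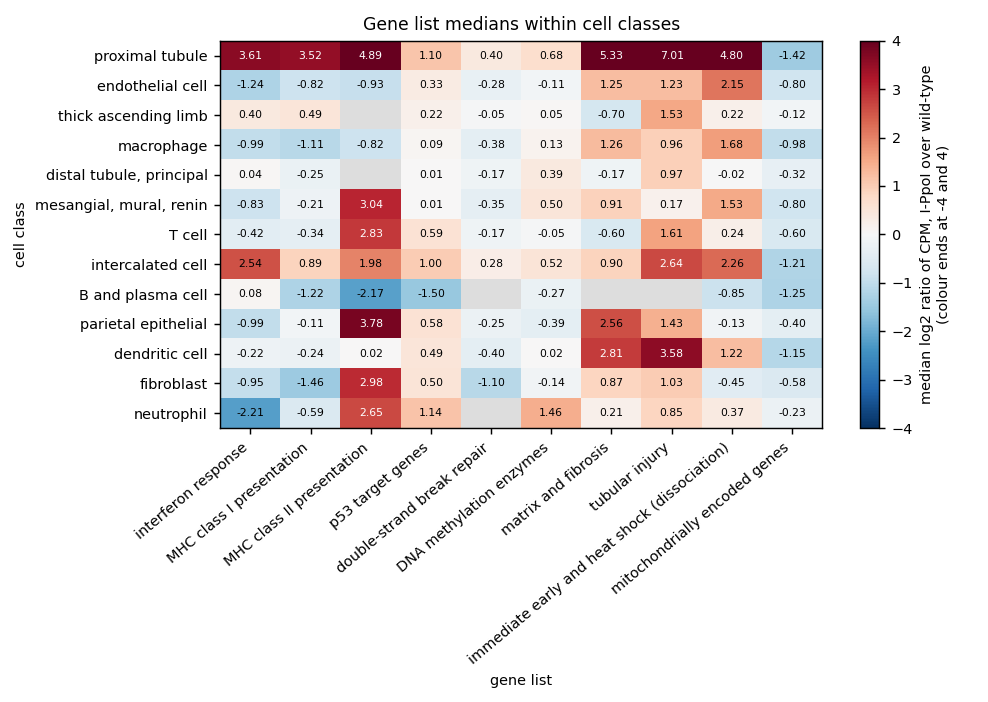
Median log2 ratio of CPM, I-PpoI over wild-type, of 10 gene lists (columns) in each cell class (rows), with the value printed in each field, red higher and blue lower; grey fields had under 3 measured members and colours end at -4 and 4. The interferon list stands at 3.61 in proximal tubule-like cells, -1.24 in endothelial-like and -0.99 in macrophage-like cells.

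The study on these mice is known to have examined kidney CD8 T cells that carry the activating receptor NKG2D, encoded by Klrk1 (chromosome 6, 129610323 to 129623864, mm10). CD8 cells, meaning cells with a UMI of Cd8a (chromosome 6, 71373427 to 71379173) or Cd8b1 (71322788 to 71337494 on the same chromosome), were a larger part of the I-PpoI library. There were 77 among 259 T cell-like cells (29.7%, 24.2 to 35.7%) against 5 among 60 (8.33%, 2.76 to 18.4%). Of all kept cells they made up 1.95% against 0.161%, a ratio of 12.1 (4.96 to 38.3). Klrk1 was seen in 30 I-PpoI cells of the class (11.6%, 7.95 to 16.1%) and 17 wild-type cells (28.3%, 17.5 to 41.4%), a ratio of 0.409 that turned to 1.21 (0.421 to 4.76) with classes from each cell's marker score. Among CD8 cells it was seen in 25 of 77 (32.5%, 22.2 to 44.1%) and in 1 of 5 (20.0%, 0.505 to 71.6%), a difference not detectable at this depth.

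The wild-type Klrk1 cells lay mostly outside the CD8 cells: 16 of 55 other cells of the class (29.1%) carried it, against 5 of 182 (2.75%) in the I-PpoI library. The wild-type class also held natural killer cell transcripts, with Ncr1 in 11 of its 60 cells and in 1 of the 259 I-PpoI cells. Among class cells with a UMI of Cd3d, Cd3e, Cd3g or Trac, Klrk1 was seen in 29 of 250 (11.6%) against 6 of 48 (12.5%), and CD8 in 76 (30.4%) against 5 (10.4%). Thinned to 1000 UMIs, which left 253 and 58 cells, CD8 stood at 21.7% against 5.17% and Klrk1 at 7.11% against 24.1%. Klrk1 among CD8 cells then stood at 10 of 55 (18.2%) against 1 of 3 (33.3%), the other way from full depth. In proximal tubule-like cells, which should lack these genes, CD8 was seen in 2 of 436 (0.459%) and 0 of 1347 (at most 0.273%), and Klrk1 in 0 of both (at most 0.843% and 0.273%), at median depths of 4732 and 3384 UMIs against 2877 and 3012 in the T cell-like class. CD8 cells with Klrk1 were 0.634% of all kept I-PpoI cells (0.410 to 0.934%) and 0.0323% of wild-type cells (0.000817 to 0.180%).

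**Figure D4:**
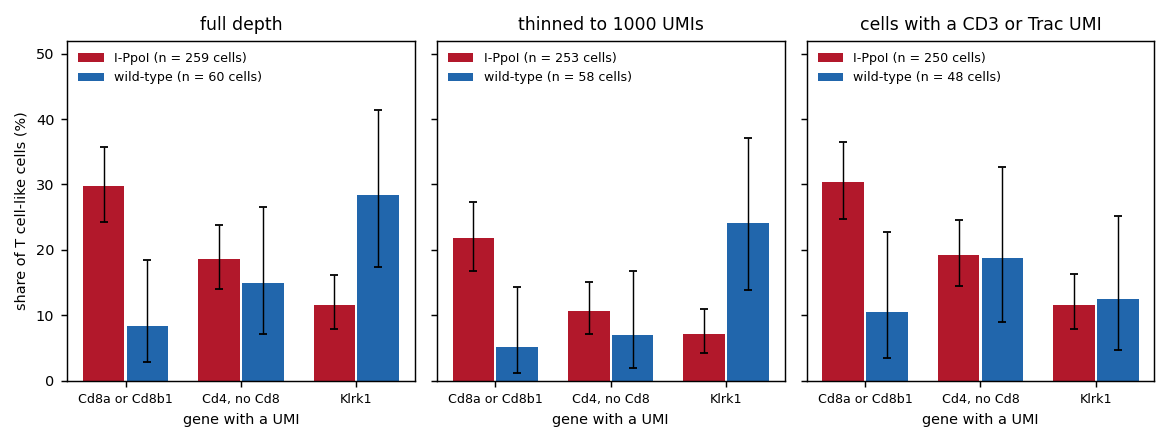
Share of T cell-like cells (%, vertical axis, starting at 0) with a UMI of Cd8a or Cd8b1, of Cd4 without either, or of Klrk1, in the I-PpoI library (red) and the wild-type library (blue), at full depth, thinned to 1000 UMIs, and among cells with a CD3 or Trac UMI; whiskers are exact binomial intervals of 95%. CD8 stands at 29.7% against 8.33% at full depth, and Klrk1 at 11.6% against 12.5% among cells with a CD3 or Trac UMI.

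By transcripts, the I-PpoI T cell-like class carried regulatory and activated T cell genes, and the wild-type class natural killer genes. All 5 regulatory T cell genes were higher (median 2.72, 2.67 at the bounds, percentile 100), with Foxp3, their defining factor, at 81 against 0 UMIs (at least 6.37-fold) and in 41 against 0 cells. Of 8 activation and exhaustion genes 7 were higher (median 2.28, 1.58 at the bounds). The checkpoint gene Ctla4 was at 200 against 0 UMIs (at least 15.7-fold), Pdcd1 at 85 against 2 (10.0-fold, 2.69 to 84.1) and Tnfrsf4, which encodes OX40, at 301 against 3 (23.7-fold, 8.02 to 115). Il7r, the interleukin 7 receptor, was 7.76-fold higher (5.30 to 11.8), and Calca and Areg were at 120 and 118 against 0 UMIs (at least 9.43-fold and 9.27-fold). Tissue residence genes were higher in 4 of 7 (median 0.95), with Itgae at 44 against 0 UMIs (at least 3.46-fold) and Cxcr6 at a ratio of 0.305 (0.247 to 0.378).

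Cytotoxic effector genes were lower in 12 of 17 (median -0.98, percentile 0). Klrk1 itself stood at 67 against 76 UMIs, a ratio of 0.208 (0.147 to 0.292), Gzma at 0.229 (0.161 to 0.326), Prf1, perforin, at 0.435 and Nkg7 at 0.465, while Gzmk was at 2.02 (0.923 to 5.24) and Ccl5 at 1.19 (1.09 to 1.30). The genes named by rank as lower were Ncr1 (3 against 52 UMIs, ratio 0.0136, 0.00272 to 0.0420), Fcer1g (19.1 times lower), Tyrobp (17.2 times), Klrb1c (14.6 times) and Klrb1f (13.9 times), which are expressed by natural killer cells. Memory T cell genes had a median of -0.54 (9 of 12 lower) and naive T cell genes of 0.01 (5 of 9 higher). The interferon list was lower in 15 of 20 (median -0.42, percentile 4.51). Median-of-ratios scaling raised the log2 ratios of this class by 0.18. Because the class mixes T and natural killer cells in unequal parts, these values compare mixtures.

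Interferon genes were mostly lower in endothelial-like and macrophage-like cells of the I-PpoI library, and a difference from the tubule was not tested. In endothelial-like cells all 25 measured interferon response genes were lower in the I-PpoI library, with a median of -1.24 (interval over members -1.42 to -0.96, percentile 0). Rsad2, the antiviral enzyme viperin, had 1582 against 5634 UMIs and a ratio of 0.386 (0.365 to 0.409), Bst2 of 0.228 (0.206 to 0.253), Ifit1 of 0.157 (0.111 to 0.216) and Ifi27l2a of 0.138 (0.102 to 0.184). All 14 MHC class I genes were lower (median -0.82), among them B2m at 0.575 (0.550 to 0.602) and their regulator Nlrc5 at 0.363. In macrophage-like cells 23 of 26 interferon genes were lower (median -0.99, interval over members -1.62 to -0.65), with Ifi27l2a at 0.253, and Irf1 and Gbp7 1.62-fold and 2.72-fold higher. All 14 MHC class I genes were lower there too (median -1.11), with H2-Q7 at 0.133 (0.100 to 0.177).

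These classes also lay in partly different clusters. Cluster 3 held 219 I-PpoI and 7 wild-type endothelial-like cells, and cluster 15 held 33 and 451. Within cluster 18, with 52 and 66 cells, the interferon median was -1.81, and within cluster 15 it was -0.94. Macrophage-like cluster 7 held 705 and 156 cells and gave a median of -0.90, while clusters 6 and 8 held 323 I-PpoI cells each with 6 and 7 wild-type cells. Some genes named for these classes lead such clusters and so describe them in part: Rsad2, Kdr and Esm1 cluster 15, Lrg1 cluster 3, C4b cluster 6 and Il1b cluster 8.

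Genes of the dissociation, matrix and senescence lists were mostly higher in endothelial-like cells of the I-PpoI library. Immediate early and heat shock genes were higher in 15 of 17 (median 2.15, percentile 100), with Fos 26.4-fold higher (22.1 to 31.8). Matrix genes were higher in 11 of 13 (percentile 100). All 11 measured genes of the senescence list were higher (median 0.90), with Cdkn1a 2.14-fold higher (1.88 to 2.43). That list includes Lmnb1, Hmgb1 and Hmgb2 and sets no direction for its members, so the count is no measure of senescence. By rank, Lrg1, which modifies TGF-beta signalling, was 44.7-fold higher (32.8 to 62.6), the smooth muscle genes Tagln and Acta2 59.2-fold and 47.8-fold, and Lyz2, a macrophage transcript, 73.4-fold (320 against 6 UMIs). Genes were screened against proximal tubule-like cells only, and RNA from other cells was not removed. Tagln, Acta2 and Lyz2 are therefore not shown to come from endothelial-like cells. Lower by rank were Gt(ROSA)26Sor (0 against 152 UMIs, a ratio of at most 0.0272 at the floor of 3 UMIs and up to 0.0338 by its interval), Ccl21a (0 against 107, at most 0.0386 at the floor), Esm1 (12.1 times lower), Cryab (12.6 times) and Fibin (3 against 125 UMIs, ratio 0.0330, 0.00672 to 0.0988). Of 7 glomerular endothelium genes 5 were lower (median -0.24, percentile 12.3), with Ehd3 at 0.330 (0.284 to 0.380) and Kdr, the VEGF receptor, at 0.462 (0.438 to 0.486). The p53 list had a median of 0.33 (14 of 23 higher, percentile 99.6).

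Macrophage activation genes were mostly higher in macrophage-like cells of the I-PpoI library. Of 13 such genes 10 were higher (median 1.36, percentile 100), with the lipid receptor gene Trem2 6.42-fold (4.88 to 8.64), Spp1 7.07-fold (4.97 to 10.4), Apoe 5.47-fold (5.33 to 5.60) and the cytokine gene Il1b 2.57-fold higher (2.32 to 2.85). By rank, C4b was at 2277 against 0 UMIs (at least 51.4-fold), fibronectin, Fn1, at 1010 against 0 (at least 22.8-fold), Cd38 at 2763 against 1 (187-fold, 33.6 to 7397), Acp5 at 1498 against 1 (102-fold, 18.2 to 4012) and Clec4n 41.8-fold higher (16.3 to 154). Mmp13 had a ratio of 0.0665 (0.0505 to 0.0877), and Dnase1l3 was 11.7 times lower, Glipr1 7.23 times, H2-Q7 7.53 times and Asb2 7.10 times. MHC class II genes were lower in 7 of 8 (median -0.82), with Cd74 at 0.547 (0.539 to 0.554) and Ctss 1.80-fold higher. Cd74, H2-Aa, H2-Ab1 and H2-Eb1 lead cluster 7 and so describe it in part. That cluster held 705 of 1351 I-PpoI and 156 of 169 wild-type cells of the class. The unfolded protein response list was lower in 10 of 11 (median -0.84, percentile 0.0100). Median-of-ratios scaling raised the log2 ratios of this class by 0.12.

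Fibroblast-like cells, with 231 I-PpoI and 18 wild-type cells, gave wide intervals for the wild-type side. Matrix genes were higher in 14 of 16 (median 0.87, percentile 100), with Timp1, an inhibitor of matrix proteases, 29.8-fold (18.0 to 53.2), Thbs1 8.60-fold (5.68 to 13.7) and Tgfb1 5.64-fold higher (2.58 to 15.4). The collagen genes Col1a1 and Col1a2 were at ratios of 1.03 (0.950 to 1.13) and 1.07 (0.984 to 1.18). Spp1 was at 83637 against 9 UMIs (307-fold, 162 to 671), Ltbp2 at 2232 against 0 (at least 24.6-fold) and Mt2 22.1-fold higher (13.6 to 38.6). The chemokine gene Cxcl12 was 49.5 times lower, Igfbp3 33.2 times, Apod at 5 against 238 UMIs had a ratio of 0.000693 (0.000223 to 0.00164), Sfrp2 at 3 against 29 UMIs had 0.00341 (0.000665 to 0.0110), and Myoc was at 0 against 22 UMIs (a ratio of at most 0.00450). Apod turned to a log2 ratio of 1.42 with a mitochondrial limit of 25 percent.

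No podocyte-like cluster was found in either library, so the cell type that carries the endonuclease could not be compared. In each library 1 barcode with podocyte genes passed both filters but was left out as a putative doublet. These I-PpoI and wild-type barcodes held 15 and 35 UMIs of Podxl, 9 and 6 of Wt1, and 0 and 10 of Nphs1. Over all kept cells Nphs1, which encodes the slit diaphragm protein nephrin (chromosome 7, 30458315 to 30487223), was at 99 against 25 UMIs, a ratio of 2.22 (1.42 to 3.59). These UMIs lay in 95 and 20 cells, and over all deposited barcodes the ratio was 1.96 (1.34 to 2.91). The podocyte list was higher in 12 of 22 genes (median 0.09, percentile 62.2), with Wt1 3.16-fold higher (2.02 to 5.17) and Podxl, which endothelium also expresses, at 0.348 (0.330 to 0.367). Of the NKG2D ligand genes 5 of 8 were measured over all cells and 4 were higher (median 2.72, 1.63 at the bounds, percentile 98.6). Ulbp1 was 3.18-fold higher (1.86 to 5.80), Raet1e was at 29 against 2 UMIs (8.12-fold, 2.05 to 70.2), Raet1d at 28 against 0 (at least 5.22-fold), H60c at 16 against 0 (at least 2.98-fold), and H60b at a ratio of 0.880 (0.311 to 2.68). These sums mix what each cell expresses with which cells were captured.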

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

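The test of macrophage against endothelial shares and the tests of Gt(ROSA)26Sor, except that of its neighbouring genes, were chosen after the result was seen, and for the others the outcome that would count for or against was written down beforehand. All patterns here were found and tested on the same 2 libraries, so any reading of them is a hypothesis.

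Interferon response genes went opposite ways between cell classes, with list medians of 3.61 in proximal tubule-like and -1.24 in endothelial-like cells, and so did MHC class I genes, with 3.52 and -0.82. The difference between the classes was not tested, and the tubular values rest on cluster 4, without which they were 0.73 and 0.98 with intervals over members that include 0 (-0.38 to 2.06 and -0.58 to 1.84). The lower interferon values are not explained by different clusters holding the endothelial and macrophage classes, because the median was still -1.81 inside the shared endothelial cluster 18 and -0.90 inside the shared macrophage cluster 7, where MHC class I medians stood at -0.97 and -1.03. RNA spilled from other cells in the wild-type droplets is argued against too, since the summed level of these genes in wild-type proximal tubule-like cells came to 1.72% of the endothelial gap. Open and untested are an effect of the genotype and a raised interferon state of the single wild-type library, which cannot be separated with 1 library per group.

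The lower proximal tubule share and higher macrophage share were weighed against cell quality. Over all deposited barcodes, each put in a class by its own markers, the proximal tubule ratio was 0.0856 (0.0723 to 0.101). The same method gave 0.0879 on kept cells, so by this method the mitochondrial limit did not produce it. The method put 14.2% of I-PpoI and 14.4% of wild-type barcodes with urothelial cells, and 95 of the 372 cells of cluster 4 with proximal tubule. It can therefore misplace barcodes, and an effect of that on the ratio was not tested. A loss of tubular cells alone would leave the other classes in proportion, but macrophage-like over endothelial-like cells stood 16.5 times higher in the I-PpoI library (13.3 to 20.4). This value follows from the share ratios of these classes already given and is no independent evidence. A difference in how the tissues dissociated or how well each class survived it was not tested and stays open beside the genotype.

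Gt(ROSA)26Sor, a long non-coding RNA gene and common transgene site (chromosome 6, 113067428 to 113077333, minus strand), had 16 UMIs in the classes of the I-PpoI library where the wild-type level of each class predicted 623, which depth and make-up of the classes do not account for. A loss over the surrounding region is argued against by the 8 nearest measured genes, whose median ratio was 0.957 (the lowest 0.648). An alteration of the locus carried by all cells needs low ratios everywhere, and the highest among the 10 classes with at least 10 predicted UMIs was 0.0657. The rule of that test was changed after its first outcome, because thick ascending limb-like cells with 0.599 predicted UMIs could not decide it (interval of the ratio up to 6.62). An inserted transgene may therefore sit at this locus in every cell, but the labels do not place one and a strain difference at the locus was not tested.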

How the results depend on the processing

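The alternatives that single out CD3 or Trac cells, that leave cluster 4 out and that use 1 cluster alone were chosen after the data were seen. No paired analysis was possible because each group has 1 library. Of 101 class shares under alternatives 73 lay within the interval of the reported value, 27 outside it and 1 in the other direction. These numbers were 30, 1 and 1 for the 32 CD8 and Klrk1 values, and 384, 48 and 1 for 433 values of 33 list medians. They were 377, 71 and 3 for 451 values of 144 gene levels, and 6, 7 and 1 for 14 sums over all cells. For list medians the interval is that over members. Other list medians were not counted. Among these, nuclear-encoded oxidative phosphorylation, NRF2 targets and megalin endocytosis in proximal tubule-like cells changed sign under an alternative, as given above. Only reported values whose interval excluded equal libraries could count as in the other direction. Klrk1 among CD8 cells, which turned when thinned, therefore counts as within its interval. Unless a cause is given beside a value, the cause was not tested.

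With a mitochondrial limit of 25 percent the share ratio was 0.315 for endothelial-like, 4.79 for macrophage-like and 0.0193 for proximal tubule-like cells, and 1.32 for thick ascending limb, whose name then went mostly to cluster 0, and the tubular injury and transport medians were 0.97 and -0.37. Log2 ratios turned to 1.42 for Apod in fibroblast-like and 0.27 for Slc7a13 and 0.24 for Slc22a30 in proximal tubule-like cells. Of the 372 cells of cluster 4, 349 passed this limit but 205 were then parietal epithelial-like, 143 unnamed and 1 proximal tubule-like. With at least 500 genes the ratio was 24.8 for fibroblast-like and 32.4 for macrophage-like cells. At resolution 0.5, where cluster 4 was unnamed, the proximal tubule ratio was 0.0280 and the medians 0.78 and -0.19, and at 2.0, where 143 of its cells were unnamed, the ratio was 0.169. By each cell's marker score the ratio was 0.0879, the medians 5.13 and -0.28, and the Klrk1 ratio in T cells 1.21. Outside the proximal tubule class the ratio was 2.15 for T cell-like, 0.242 for endothelial-like and 3.99 for macrophage-like cells, by construction of the denominator. Among CD3 or Trac cells the Klrk1 ratio was 0.928. Without cluster 4 the proximal tubule ratio was 0.0373 and the medians 1.29, with an interval over members that includes 0, and -0.32. In cluster 14 alone the injury median was 1.33 and the male-biased median 0.0045, against a negative one in the whole class. The endothelial interferon median was -1.81 in cluster 18 and -0.94 in cluster 15. Without mitochondrial genes in the total Eif2s3y stood at -0.10 over all cells.

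Some alternatives gave no value: the parietal epithelial share at resolution 0.5 and at 500 genes, the fibroblast matrix list at 500 genes, and Havcr1, Sox9, Tubb2b, Vcam1 and Myoc at the 25 percent limit. Depth limits what few wild-type cells can show, above all the 5 CD8 cells, the 12 neutrophil-like cells and the 18 fibroblast-like cells.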

Other observations

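No test was run for this part, and which of its lists and named genes to describe was chosen after their values were seen.

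Intercalated-like cells, with 46 I-PpoI and 56 wild-type cells, had higher interferon and injury genes. Their quality differed as well, with 8.98% against 20.1% mitochondrial UMIs and 1 against 23 cells above 25 percent. With that limit the interferon and injury medians were 2.54 and 2.06. All 15 interferon genes were higher (median 2.54, 2.52 at the bounds), as were all 12 injury genes (median 2.64, 2.44 at the bounds) and 17 of 19 p53 targets (median 1.00). All 18 nuclear-encoded oxidative phosphorylation genes were lower (median -0.79). The epithelial stress factor gene Klf4 stood at 491 against 0 UMIs (at least 165-fold), while the anion exchanger gene Slc4a1 was 8.53 times lower and Klk1 6.20 times, the last at a log2 ratio of -1.11 with the 25 percent limit. Genes of other cell types differed too: Krt19 (186 against 0 UMIs), Sprr2f (139 against 0) and Sprr1a (113 against 0), which lead the unnamed cluster 0, were higher, and the thick ascending limb genes Egf (1 against 117) and Slc12a1 (0 against 67) lower, and RNA or cells of other types in the class were not tested for. Totals without mitochondrial genes lowered the log2 ratios of this class by 0.19 and median-of-ratios scaling by 0.20. In parietal epithelial-like cells 13 of 16 matrix genes were higher (median 2.56, 2.41 at the bound), with fibronectin, Fn1, at 611 against 3 UMIs (73.8-fold, 25.1 to 359), while the interferon target Cxcl10 was at 1 against 66 UMIs (ratio 0.00549, 0.000137 to 0.0317). In thick ascending limb-like cells the injury gene Lcn2 was 141-fold higher (79.3 to 265), and Egf, a product of that segment, was at 2 against 15971 UMIs in classes of 25 and 243 cells. Of these cells, 20 and 169 were above 25 percent mitochondrial UMIs. Lcn2 also leads the unnamed cluster 0, and RNA or cells of other types were not tested for here either. Median-of-ratios scaling raised the log2 ratios of parietal epithelial-like cells by 0.24 and lowered those of thick ascending limb-like cells by 0.39.

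Among blood cells, the B and plasma-like class, with 30 cells in each library, held far more antibody transcripts in the I-PpoI library. Jchain, the joining chain of secreted antibodies, stood at 15399 against 0 UMIs (at least 1249-fold higher), and Igha, the IgA heavy chain, at 21069 against 3 (1709-fold, 585 to 8286). The MHC class II genes Cd74 (823 against 966 UMIs) and H2-Aa (229 against 249) were present in both. They also lead macrophage-like cluster 7 and so are not specific to B cells. With Jchain absent from the wild-type cells, the class was a different mixture in each library. These antibody UMIs enlarge the I-PpoI total, 341249 against 83023 UMIs, which lowers the CPM of every other gene there. Neutrophil-like cells had all 7 interferon genes lower (median -2.21), with Ifi27l2a 54.6 times and Ifitm3 9.13 times lower, and the chemokine gene Ccl3 at 2012 against 0 UMIs (at least 57.7-fold higher), from 12 wild-type cells. In dendritic-like cells Ccl17 was at 491 against 2 UMIs (81.7-fold, 22.5 to 677) and Cd209a was 5.09 times lower. Median-of-ratios scaling raised the log2 ratios by 1.36 in B and plasma-like, 0.29 in neutrophil-like and 0.12 in dendritic-like cells. Over all kept cells all 16 cell cycle genes were higher (median 1.69, percentile 100), all 14 genes of water and sodium transport in the collecting system were lower (median -2.11), and the sex-linked list stood at -0.10. Such sums follow which cells were captured, and the second list includes the thick ascending limb genes Umod and Slc12a1, whose class had a share ratio of 0.0808. Xist had 3 against 1 UMIs and the Y-linked Ddx3y 1946 against 1063, so both libraries carried a male profile.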
